A study of Mus musculus with 15 samples.

How the data were processed

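The study holds 15 RNA-seq libraries of primary microglia from mouse brain, 3 each of control, myelin, atorvastatin, negative control and pparg over expression, grouped by the treatment that the labels give. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was captured on beads and fragmented, and the amplified libraries were sequenced on an Illumina NovaSeq. The labels name no batch, culture, animal, dose or time, and do not state whether reads were stranded, so that values of overlapping, antisense or closely related genes are uncertain. They do not define the negative control, and they do not say whether atorvastatin, negative control or pparg over expression cells had also received myelin.

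The authors deposited 1 table of 21956 genes with an estimated count and a TPM for each library. The deposited counts are estimated (expected) counts with no normalization, per the file headers and the values: on average 7.22% of the values carried a fraction and held 15.2% of the counts, and totals differed between libraries. The deposited TPM values are scaled within each library, and each column sums to 1000000. HISAT2 2.1.0, StringTie 1.3.1 and RSEM are named in the submitters' processing notes without their role or order, and neither the genome build nor the annotation is given in the sources used here. Genes were taken by the symbols in the table; 83 IDs had no symbol and 22 repeated one, and these were kept under their ID. All value columns were matched to a sample.

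Counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10) left 13630 genes, TMM factors ran from 0.907 to 1.15, and 1 quasi-likelihood model of the 5 groups was fitted to all 15 libraries (biological coefficient of variation 0.0565). The p-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 5%. The comparisons were myelin and atorvastatin against control, atorvastatin against myelin, pparg over expression against negative control, and negative control against control. The standard error of a log2 fold change is its size divided by the square root of its quasi-likelihood F. Fold changes are on the TMM scale and levels on the TPM scale, and these differ where the most abundant genes change, as they did here: the 10 genes with most counts took 10.7% of counts in control and 16.8% in atorvastatin. All p-values measure only the spread between these libraries, since the labels do not say that libraries of a group come from separate cultures or animals.

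Before the data were examined, 20 biology lists and 10 lists of markers of other cell types and of sample quality were written, with 536 genes, of which 528 were found by symbol (not found were Atp5a1, Atp5b, Atp5c1, Atp5o, Ddx58, Fcrls and Mx2 among others). Lists were tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset correlation of 0.01, adjusted over the biology lists and over the composition lists separately. Members are counted as past 5% over all genes, and again with adjustment over the list alone. Each call was repeated with the correlation estimated from the residuals. Cell-type levels are sums of TPM over the listed markers. The genes named in the text follow a rule made before the data were examined. These are per comparison the 5 largest rises and falls past 5% with a mean of at least 5 TPM and groups that do not overlap, up to 2 members of each list with the smallest p, and 13 anchor genes such as Pparg and Abca1. Srebf1, Sqle and pathway genes in the closing section, were chosen after their values were seen. Results for some genes and for 1 list are not reported here.

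The tests were tried on counts simulated from the means of the control and negative control libraries, with 200 genes changed per comparison. At 3 against 3 libraries, edgeR recovered 37.3% of 1.25-fold, 70.1% of 1.5-fold and 84.8% of 2-fold changes in the comparison of myelin with control. Of its calls 14.1% were false, above the intended 5%. It recovered 48.5%, 62.7% and 83.3% with 3.01% false calls for pparg over expression against negative control. Camera called the changed list and 0 of 19 unchanged lists, and fry called 1 of the 19. Each gene was drawn independently there, so these list results cannot show how the preset correlation behaves where genes are correlated. At these depths (15.5 to 19.8 counts per library, in units of 1000000), most 1.25-fold changes would be missed.

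Alternatives set before the data were examined were DESeq2 1.42.0 size factors within edgeR, the DESeq2 Wald test, limma-trend on log2(TPM + 1), no filter on low counts, only the genes above the median in mean count, only the 2 groups compared in the fit, a minimum fold of 2, the replicate number as a block, and leaving out each library of the 2 groups in turn. For the lists, camera with an estimated correlation and fry were run as well. Added after seeing the data were scaling on library totals alone, scaling on 20 macrophage genes chosen because markers of other cells differed between groups, and leaving out 3901 genes at least 2-fold higher in control than in negative control. A pseudocount of 0.1 in place of 1 was planned for tables without counts and does not apply to a count test. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.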

Results

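RNA was sequenced from primary microglia, the resident macrophages of the brain, isolated from mouse brain. The 15 libraries fall into 5 groups of 3: control, myelin, atorvastatin, negative control and pparg over expression. Myelin is the lipid-rich membrane around axons that microglia take up and digest. Atorvastatin is a statin, an inhibitor of the rate-limiting enzyme of cholesterol synthesis. Pparg encodes a nuclear receptor that fatty acids activate. The series' design text also names a virus, and the negative control group was read as the control for the pparg over expression group. The labels do not say what the negative control cells received, nor whether cells of the atorvastatin, negative control and pparg over expression groups had also been given myelin. Library totals, in units of 1000000 estimated counts, ran from 15.5 to 19.8, and group means from 16.5 ± 0.43 in control to 17.9 ± 1.67 in atorvastatin (SD, n = 3 each). In what follows, ± after a log2 fold change is its standard error, ± after a TPM (transcripts per 1000000) is the SD, and n = 3 in each group.

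The groups differed in transcripts of other brain cell types. Astrocyte markers (Gfap, Aqp4, Slc1a2 and 9 more) summed to 1682 ± 133 TPM in control, 1331 ± 34.7 in myelin, 719 ± 60.5 in atorvastatin, 40.7 ± 8.30 in negative control and 76.8 ± 5.01 in pparg over expression libraries. Markers of oligodendrocytes and myelin (Mbp and others) went from 705 ± 59.2 TPM in control to 517 ± 36.9 in myelin, 175 ± 16.5 in atorvastatin, 83.5 ± 4.40 in negative control and 95.6 ± 1.08 in pparg over expression. Neuron markers summed to 164 ± 8.55, 109 ± 11.7, 63.4 ± 1.74, 2.85 ± 0.27 and 5.09 ± 2.29 TPM in the same order. Control libraries had 12946 ± 46.2 genes at 1 TPM or more, against 10616 ± 36.2 in negative control. The first principal component of log2(TPM + 1) took 87.1% of the variance and ran from control, myelin and atorvastatin on one side to negative control and pparg over expression on the other. The second took 5.99% and set atorvastatin apart. Libraries of one group correlated across genes at r = 0.996 to 0.998, against 0.919 to 0.997 for pairs from different groups, and no pair of replicates matched within sampling noise (chi-square per gene 2.11 to 7.30).

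**Figure D1:**
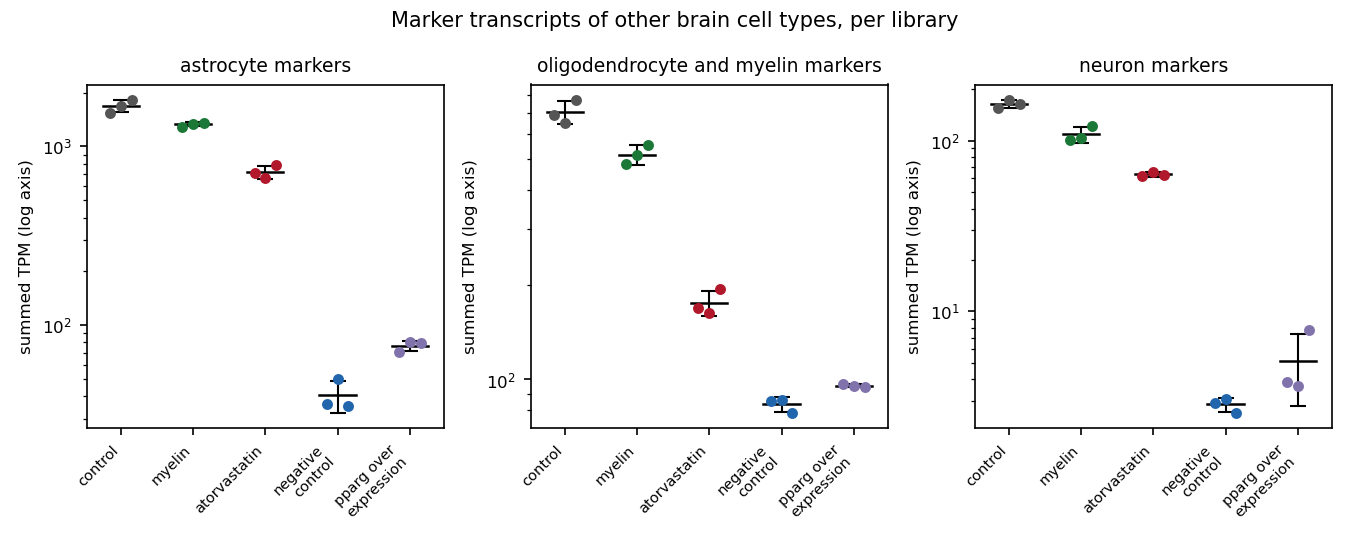
Summed TPM (log axis) of astrocyte, oligodendrocyte and myelin, and neuron marker genes in each library, by group; points are libraries, horizontal bars the mean of 3 and vertical bars the SD. Control libraries were highest in all 3 panels, and negative control libraries lowest on average, with 40.7 TPM of astrocyte markers against 1682 in control.

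Pparg itself was read first, because it checks the label of the over expression group. Its level was 32.9 ± 2.06 TPM in the libraries labelled pparg over expression and 29.1 ± 3.46 TPM in negative control, a log2 fold change of 0.25 ± 0.09 that did not pass after adjustment over 13630 genes (edgeR adjusted p = 0.0751). Taken as a single gene without adjustment, its fold of 1.19 by edgeR had a 95% interval of 1.04 to 1.35, which leaves out no change. An exact two-sided permutation test of the TPM values gave p = 0.2, where 3 against 3 libraries cannot go below 0.1. The libraries of both groups were above the other 3 groups, which had 13.7 ± 1.44 (control), 18.7 ± 1.16 (atorvastatin) and 18.7 ± 0.84 TPM (myelin). Without negative control replicate 2 the log2 fold change was 0.32 and passed (edgeR adjusted p = 0.0377, against 0.0565 to 0.268 over the alternatives that kept all libraries). The table therefore shows at most a small rise of Pparg to go with the label, and these are called the libraries labelled pparg over expression throughout.

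Libraries of the myelin group had lower transcripts of cholesterol synthesis and uptake than control libraries, and higher transcripts of cholesterol export and fatty acid handling. Both groups are mixtures of cell types, so these changes cannot be assigned to microglia alone. When libraries were scaled on macrophage genes, the median rise was 0.032 for the export list and 0.15 for PPAR targets, smaller than in the main test. The median of fatty acid oxidation was then below 0, at −0.12. Cyp51, a demethylase of sterol precursors, went from 50.5 ± 1.95 to 25.1 ± 1.12 TPM, a log2 fold change of −0.88 ± 0.05 (edgeR adjusted p = 3.32e-11). Abcg1, a cholesterol exporter, rose from 32.1 ± 3.20 to 75.9 ± 3.35 TPM (1.24 ± 0.07, edgeR adjusted p = 3.32e-11). Angptl4, a secreted lipase inhibitor induced by PPAR receptors, rose by 1.76 ± 0.08, and Cd36, a fatty acid and lipoprotein receptor, by 1.01 ± 0.07. Plin2, the main coat protein of lipid droplets in macrophages, rose from 1654 ± 119 to 2735 ± 98.6 TPM (0.89 ± 0.06, edgeR adjusted p = 4.14e-10).

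Of the 20 cholesterol synthesis genes, 17 fell and 0 rose, and 18 fell when adjusted over the list alone (median log2 fold −0.58, camera adjusted p = 2.36e-20; adjusted p = 0.00829 with an estimated correlation). Beside Cyp51, Msmo1, an oxidase of the same demethylation, changed by −0.73 ± 0.05. Of 6 measured genes of SREBP2-regulated uptake and feedback, 5 fell, also when adjusted over the list alone (median −0.63, camera adjusted p = 2.57e-08). Srebf2, which encodes the transcription factor of this program, changed by −0.56 ± 0.04. Of 15 genes of cholesterol efflux and LXR targets, 11 rose and 1 (Srebf1) fell, with 12 rising when adjusted over the list alone (median 0.36, or 0.23 on the TPM scale and 0.032 with macrophage-gene scaling, where 7 rose and 3 fell; camera adjusted p = 3.95e-09). Among them were Abca1 at 0.81 ± 0.07, Mylip, a ubiquitin ligase gene induced by LXR, at 0.80 ± 0.05, and Apoe at 0.68 ± 0.04. PPAR targets rose in 14 of 19 with 0 falling, the same count when adjusted over the list alone (median 0.48, or 0.28 on the TPM scale and 0.15 with macrophage-gene scaling, where 7 rose and 1 fell; camera adjusted p = 3.09e-11). They were led by Angptl4 and the mitochondrial carrier Ucp2 (0.84 ± 0.04). Pparg rose by 0.60 ± 0.10, Lpl, which releases fatty acids from lipoproteins, by 0.39 ± 0.08, and Fabp4, a fatty acid carrier, by 0.39 ± 0.09. Lpl (0.059) and Fabp4 (0.074) were no longer called with macrophage-gene scaling.

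Fatty acid synthesis fell in 9 of 15 genes and rose in 1 (10 and 1 when adjusted over the list alone; median −0.28, camera adjusted p = 6.19e-06). The desaturases followed, Scd1 at −0.76 ± 0.08 and Scd2 at −0.56 ± 0.05. Fatty acid oxidation rose in 12 of 22 with 0 falling, also when adjusted over the list alone (median 0.21, camera adjusted p = 7.11e-08), although the median was −0.12 when libraries were scaled on macrophage genes. Cpt1a, which admits fatty acids to mitochondria, rose by 0.58 ± 0.04 and Hadha by 0.45 ± 0.04, the latter at 0.12 and not called with macrophage-gene scaling. With an estimated correlation the adjusted p of these 5 lists, from SREBP2-regulated uptake to fatty acid oxidation, were 0.00998, 0.0337, 0.00998, 0.0413 and 0.0201. Lysosome genes rose in 28 of 31 and fell in 1 (29 and 1 when adjusted over the list alone; median 0.29, or −0.04 with macrophage-gene scaling), including Psap (0.72 ± 0.06) and Ctsa (0.46 ± 0.04). Phagocytic receptors rose in 15 of 25 and fell in 3 (the same when adjusted over the list alone; median 0.20, or −0.13 with macrophage-gene scaling). Mertk, a receptor for dying cells, rose by 0.61 ± 0.04 and Trem2, a lipid receptor of microglia, by 0.25 ± 0.04, or −0.081 with macrophage-gene scaling. Genes of disease-associated microglia rose in 16 of 28 and fell in 1 (17 and 1 when adjusted over the list alone; median 0.25, or −0.07 with macrophage-gene scaling). The camera adjusted p of these 3 lists were 4.22e-20, 2.13e-06 and 1.02e-06, and each call was lost with an estimated correlation (adjusted p = 0.0888, 0.22 and 0.111). Lipid droplet genes (8 rose and 1 fell of 18, 9 and 2 when adjusted over the list alone, median 0.18) and NRF2 oxidative stress genes (9 rose and 1 fell of 18, 9 and 3 when adjusted over the list alone, median 0.20) passed camera at adjusted p = 0.0034 and 0.0118, and not with an estimated correlation (adjusted p = 0.128 and 0.36). Both medians were below 0 with macrophage-gene scaling, at −0.15 and −0.13.

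Interferon response genes fell in 16 of 30 with 0 rising, 20 when adjusted over the list alone (median −0.49, camera adjusted p = 1.02e-06; adjusted p = 0.22 with an estimated correlation). Ifi27l2a was at −1.12 ± 0.18 and Ifit3 at −0.77 ± 0.14. Proliferation genes fell in 14 of 26 and 1 rose, the same when adjusted over the list alone (median −0.25, camera adjusted p = 0.00154; adjusted p = 0.303 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at −0.62 ± 0.10. The other 7 lists did not pass, and their members moved both ways, although more fell than rose in each with macrophage-gene scaling. P2ry12, a purine receptor of resting microglia, changed by −0.67 ± 0.08. The cytokine Il1a rose by 1.13 ± 0.14 and Tnf by 0.58 ± 0.13, while Ptgs2, the inducible cyclooxygenase, fell (−1.23 ± 0.13). The call of Tnf was lost with macrophage-gene scaling (0.26). Il1b was at 0.35 ± 0.23 (edgeR adjusted p = 0.275). Among the largest rises were the scavenger receptors Marco (1.96 ± 0.26), itself a member of the phagocytic receptor list, and Stab2 (1.32 ± 0.10). Il18bp (1.47 ± 0.16) and Rsc1a1 (2.09 ± 0.64, not past the threshold by the Wald test or without control replicate 2 or 3 or myelin replicate 1) were others. The largest falls were in Cavin2 (−1.48 ± 0.27), Fhl2 (−1.44 ± 0.32), the chemokine Ccl12 (−1.44 ± 0.37), Lurap1l (−1.43 ± 0.19) and Tinagl1 (−1.28 ± 0.19). Beside these groups, astrocyte, oligodendrocyte and neuron markers had median log2 folds of −0.19, −0.33 and −0.44, with 3 members of each past the threshold, all lower (camera adjusted p = 0.0804, 0.0804 and 0.0903).

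In total 3810 of 13630 tested genes passed 5% by edgeR between myelin and control, 2151 higher and 1659 lower; 29 were higher and 96 lower by at least 2-fold. The split depended on the scaling: it was 1664 higher and 2100 lower with DESeq2 size factors, 801 and 3142 with limma on TPM, 1060 and 3333 with library totals, and 200 and 8319 when libraries were scaled on 20 macrophage genes. These scalings moved the median log2 fold of all genes by −0.12 (TPM), −0.11 (totals) and −0.33 (macrophage genes), so that a change given here is relative to the trimmed mean of all genes in the library. Medians of falling lists were lower with the last, at −0.91 for cholesterol synthesis, −0.96 for SREBP2-regulated uptake, −0.61 for fatty acid synthesis, −0.81 for interferon response and −0.58 for proliferation. On the TPM scale fatty acid oxidation, lipid droplet, lysosome, phagocytic, disease-associated and NRF2 medians were 0.095, 0.051, 0.16, 0.068, 0.13 and 0.051, and that of proliferation −0.38.

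**Figure D2:**
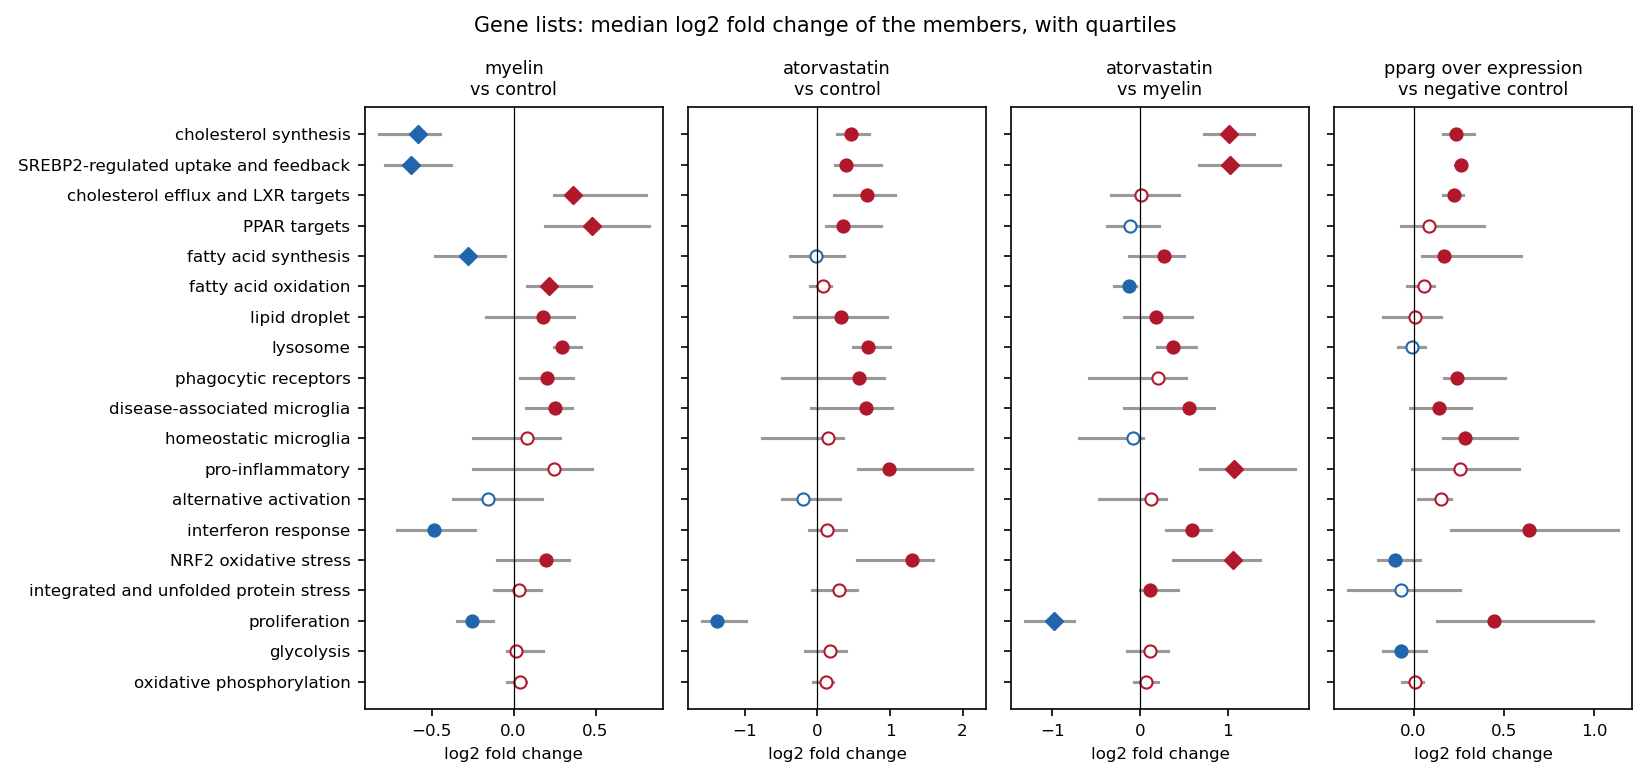
Median log2 fold change of the measured genes of each of 19 gene lists (points) with quartiles (grey lines) in 4 comparisons; filled points passed camera at 5% with a preset correlation, diamonds also with an estimated correlation, open points did not pass, red is above 0 and blue below. Cholesterol synthesis lay at −0.58 with myelin against control and at 1.01 with atorvastatin against myelin, both diamonds; lysosome, phagocytic and fatty acid oxidation medians above 0 with myelin turned below 0 when libraries were scaled on macrophage genes.

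Libraries of the atorvastatin group, which are mixtures of cell types, had higher oxidative stress, inflammatory and lysosomal transcripts than control libraries and lower transcripts of cell division. The list calls behind this rest on a preset correlation between genes, and 0 of the 20 lists passed camera with an estimated one. The lysosomal rise was also small when libraries were scaled on macrophage genes. Srxn1, which restores oxidised peroxiredoxins, rose from 98.1 ± 5.87 to 352 ± 11.7 TPM (2.16 ± 0.06, edgeR adjusted p = 1.07e-17). Slc7a11, the cystine importer, rose from 3.66 ± 0.61 to 23.9 ± 1.77 TPM (3.02 ± 0.10, edgeR adjusted p = 9.25e-17). Tnf rose by 2.14 ± 0.12 and Il1b by 2.16 ± 0.21 on the log2 scale. Mki67, a marker of dividing cells, went from 39.9 ± 2.79 to 9.95 ± 0.24 TPM (−1.65 ± 0.09, edgeR adjusted p = 3.45e-13). P2ry12 went from 61.1 ± 7.39 to 10.96 ± 0.82 TPM (−1.93 ± 0.09, edgeR adjusted p = 3.33e-14).

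NRF2 oxidative stress genes rose in 15 of 18 and fell in 2, the same when adjusted over the list alone (median 1.299, or 0.68 with macrophage-gene scaling; camera adjusted p = 1.65e-08; adjusted p = 0.118 with an estimated correlation). Pro-inflammatory genes rose in 20 of 25 with 0 falling, 21 when adjusted over the list alone (median 0.99, or 0.38 with macrophage-gene scaling, where 12 rose and 5 fell; camera adjusted p = 2.18e-05; adjusted p = 0.118 with an estimated correlation). The adhesion molecule Icam1 rose by 1.28 ± 0.06. Lysosome genes rose in 29 of 31 and fell in 1, the same when adjusted over the list alone (median 0.70, or 0.093 with macrophage-gene scaling, where 14 rose and 7 fell; camera adjusted p = 1.32e-14; adjusted p = 0.173 with an estimated correlation). The proton pump subunit Atp6v0d2 rose by 1.79 ± 0.06 and the lysosomal lipase Lipa by 1.40 ± 0.05. Genes of disease-associated microglia rose in 19 of 28 and fell in 7, the same when adjusted over the list alone (median 0.66, or 0.052 with macrophage-gene scaling, where 12 rose and 9 fell; camera adjusted p = 0.000175; adjusted p = 0.186 with an estimated correlation). Gpnmb and Lgals3, both raised in lipid-laden macrophages, were at 1.58 ± 0.06 and 1.55 ± 0.06. Phagocytic receptors rose in 16 of 25 and fell in 8, the same when adjusted over the list alone (median 0.57, or −0.04 with macrophage-gene scaling; camera adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation). Mfge8, a bridge to dying cells, rose by 1.39 ± 0.05, Mertk by 1.01 ± 0.04 and Trem2 by 0.57 ± 0.04, with Trem2 at −0.040 under macrophage-gene scaling. Over the same comparison the median of astrocyte markers was −1.06 (11 of 12 lower, camera adjusted p = 0.000677; adjusted p = 0.286 with an estimated correlation). That of oligodendrocyte and myelin markers was −2.29 (13 of 14 lower, camera adjusted p = 8.22e-06; adjusted p = 0.0493 with an estimated correlation).

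Cholesterol synthesis genes rose in 15 of 20 and fell in 2, the same when adjusted over the list alone. The median was 0.46, and 0.14 on the TPM scale and −0.15 with macrophage-gene scaling (camera adjusted p = 0.000379; adjusted p = 0.173 with an estimated correlation). Mvd, of the mevalonate pathway, rose by 1.38 ± 0.10 and Msmo1 by 0.74 ± 0.04, or 0.13 and not called with macrophage-gene scaling. Sqle was among the members that fell. Genes of SREBP2-regulated uptake rose in 5 of 6 with 0 falling, also when adjusted over the list alone (median 0.40, or −0.22 with macrophage-gene scaling; camera adjusted p = 0.0085, and adjusted p = 0.173 with an estimated correlation). Insig1, a partner of the sterol sensor, rose by 1.002 ± 0.05. Efflux and LXR targets rose in 11 of 15 and fell in 2 (11 and 3 when adjusted over the list alone; median 0.68, or 0.072 with macrophage-gene scaling, where 5 rose and 7 fell; camera adjusted p = 0.00104; adjusted p = 0.186 with an estimated correlation). Mylip rose by 1.24 ± 0.05, the phospholipid transfer protein gene Pltp by 1.04 ± 0.05, Apoe by 0.68 ± 0.04 and Abca1 by 0.30 ± 0.07. However, Abca1 was at −0.0075 on the TPM scale and was called lower (−0.31) with macrophage-gene scaling. That scaling also ended the call of Apoe (0.072), and Abca1 lost its call by the Wald test (0.20), in genes above the median count (0.15) and with library totals (0.048). PPAR targets rose in 12 of 19 and fell in 2, the same when adjusted over the list alone (median 0.35, or −0.26 with macrophage-gene scaling; camera adjusted p = 0.00194, and adjusted p = 0.173 with an estimated correlation). Fabp4 was at 1.57 ± 0.08, Angptl4 at 1.502 ± 0.08, Fabp5 at 1.28 ± 0.06, Cd36 at 0.92 ± 0.07 and Pparg at 0.75 ± 0.10, or 0.14 and not called with macrophage-gene scaling. Lpl was at −0.04 ± 0.08 (edgeR adjusted p = 0.694), but was called lower on the TPM scale (−0.34), with library totals (−0.29) and with macrophage-gene scaling (−0.65). Lipid droplet genes rose in 12 of 18 and fell in 5, the same when adjusted over the list alone (median 0.33, or −0.28 with macrophage-gene scaling; camera adjusted p = 0.00761, and adjusted p = 0.173 with an estimated correlation). Those that rose most were lipases that empty droplets, Mgll at 2.22 ± 0.07 and Pnpla2 at 1.44 ± 0.04, beside Plin2 at 0.69 ± 0.06, or 0.084 and not called with macrophage-gene scaling. Fatty acid synthesis (5 rose and 6 fell of 15, camera adjusted p = 0.885) and fatty acid oxidation (7 rose and 5 fell of 22, camera adjusted p = 0.606) did not pass. Their members mostly fell with macrophage-gene scaling, 11 and 19 with 1 and 0 rising, and on the TPM scale 7 and 14 fell with 3 and 2 rising.

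Proliferation genes fell in 25 of 26 with 0 rising, also when adjusted over the list alone (median −1.38, camera adjusted p = 6.76e-11; adjusted p = 0.118 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was at −1.56 ± 0.09. Their fall went with the falls of the astrocyte and oligodendrocyte markers given above. Immediate early genes, which mark recent stimulation or handling, fell in 9 of 12 and rose in 2, the same when adjusted over the list alone (median −0.97, camera adjusted p = 0.0221; adjusted p = 0.286 with an estimated correlation). Homeostatic microglia genes moved both ways (10 rose and 8 fell of 19, median 0.15 and mean −0.25, camera adjusted p = 0.885), but 4 rose and 8 fell on the TPM scale (median −0.091), 4 and 9 with library totals (−0.11) and 2 and 14 with macrophage-gene scaling (−0.46), with the TGF-beta receptor Tgfbr1 at 1.18 ± 0.04 against P2ry12 at −1.93 ± 0.09. The stress transcription factor Atf3 rose by 1.34 ± 0.05 and Phgdh, of serine synthesis, fell (−1.41 ± 0.10) in a list that did not pass (13 rose and 4 fell of 23, camera adjusted p = 0.0818), where 6 rose and 11 fell on the TPM scale, 6 and 10 with library totals and 4 and 15 with macrophage-gene scaling. Fn1, fibronectin, changed by −1.69 ± 0.12 within the alternative activation list (3 rose and 4 fell of 10, or 1 and 8 with macrophage-gene scaling; camera adjusted p = 0.77). The largest rises were Tpm3-rs7 (5.82 ± 0.15), Bcl2a1a (4.11 ± 0.25), H2-M2 (4.08 ± 0.24), Dcn (3.92 ± 0.27) and Prl2c2 (3.89 ± 0.53). Apart from Dcn these belong to gene families, and reads shared between relatives were not examined. Dcn, a fibroblast gene, varied between atorvastatin libraries (28.9 ± 8.72 TPM). The largest falls were Sprr2b (−4.07 ± 0.83, also of a gene family), Shh (−3.76 ± 0.28), Crabp1 (−3.53 ± 0.45), Klhdc8a (−3.47 ± 0.18) and Tnr, an extracellular matrix gene of glia, at −3.47 ± 0.10.

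Between atorvastatin and control 8735 of 13630 genes passed 5% by edgeR, 4470 higher and 4265 lower, with 487 higher and 2093 lower by at least 2-fold. The split was 3287 higher and 5158 lower with DESeq2 size factors, 1586 and 6925 with limma on TPM, 1979 and 6879 with library totals and 665 and 10740 with macrophage-gene scaling. These moved the median of all genes by −0.10, −0.30, −0.25 and −0.61. On the TPM scale the medians of SREBP2-regulated uptake, efflux, lipid droplet, lysosome, phagocytic and disease-associated genes were 0.098, 0.37, 0.088, 0.40, 0.26 and 0.38, and that of PPAR targets was 0.096 with library totals.

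Set against myelin rather than control, atorvastatin libraries were higher in every listed gene of cholesterol synthesis. Insig1 was at 111 ± 4.49 TPM with atorvastatin and 38.8 ± 0.56 with myelin (log2 fold 1.70 ± 0.06, edgeR adjusted p = 3.61e-16). Msmo1 was higher by 1.47 ± 0.04 and Cyp51 by 1.27 ± 0.05. The cholesterol exporter Abca1 was lower, at 225 ± 5.53 against 363 ± 6.35 TPM (−0.51 ± 0.07, edgeR adjusted p = 3.23e-06). Apoe did not differ by the main test (0.01 ± 0.04, edgeR adjusted p = 0.907). It was called lower on the TPM scale (−0.18), with library totals (−0.14) and with macrophage-gene scaling (−0.27).

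All 20 cholesterol synthesis genes were higher with atorvastatin, also when adjusted over the list alone (median 1.01, camera adjusted p = 6.47e-15; adjusted p = 0.0259 with an estimated correlation). So were 5 of 6 genes of SREBP2-regulated uptake, also when adjusted over the list alone (median 1.03, camera adjusted p = 5.38e-06; adjusted p = 0.0366 with an estimated correlation). Fatty acid synthesis was higher in 8 of 15 and lower in 2 (9 and 2 when adjusted over the list alone; median 0.28, and −0.0043 with macrophage-gene scaling; camera adjusted p = 0.0274, and adjusted p = 0.269 with an estimated correlation). Fasn, fatty acid synthase, was at 0.80 ± 0.05. Fatty acid oxidation was lower in 11 of 22 with 0 higher, also when adjusted over the list alone (median −0.13, or −0.31 on the TPM scale and −0.41 with macrophage-gene scaling; camera adjusted p = 0.000815; adjusted p = 0.133 with an estimated correlation). The thioesterase gene Acot1 was at −1.26 ± 0.09 and Hadhb at −0.41 ± 0.04. Efflux and LXR targets (5 higher and 4 lower of 15, or 5 and 10 with macrophage-gene scaling; camera adjusted p = 0.365) and PPAR targets (4 higher and 8 lower of 19, or 3 and 12 with macrophage-gene scaling; camera adjusted p = 0.331) did not pass. Nr1h3, which encodes an LXR receptor, was higher by 1.68 ± 0.15 and Fabp4 by 1.18 ± 0.08, while Lpl was lower (−0.43 ± 0.08). Cd36 (−0.09 ± 0.07, edgeR adjusted p = 0.289) and Pparg (0.15 ± 0.10, edgeR adjusted p = 0.205) did not pass. Cd36 was called lower on the TPM scale (−0.23), in genes above the median count (−0.18), with library totals (−0.24), with macrophage-gene scaling (−0.37) and without genes high in control cultures (−0.19), while Pparg was at −0.0022 on the TPM scale and −0.13 with macrophage-gene scaling. Lipid droplet genes were higher in 8 of 18 and lower in 4 (9 and 4 when adjusted over the list alone; median 0.18, or −0.10 with macrophage-gene scaling; camera adjusted p = 0.015, and adjusted p = 0.222 with an estimated correlation). Plin2 was lower (−0.19 ± 0.06) and Mgll higher by 1.65 ± 0.07. Beside these lists, astrocyte markers were lower in 11 of 12 (median −0.89, camera adjusted p = 0.00113; adjusted p = 0.339 with an estimated correlation). Oligodendrocyte and myelin markers were lower in 12 of 14 (median −2.00, camera adjusted p = 1.5e-06; adjusted p = 0.0336 with an estimated correlation).

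NRF2 oxidative stress genes were higher in 16 of 18 with 0 lower, also when adjusted over the list alone (median 1.06, camera adjusted p = 4.54e-12; adjusted p = 0.0366 with an estimated correlation). Slc7a11 was at 3.19 ± 0.10 and Srxn1 at 1.94 ± 0.06. Pro-inflammatory genes were higher in 20 of 25 and lower in 2, the same when adjusted over the list alone (median 1.08, camera adjusted p = 4.47e-07; adjusted p = 0.0366 with an estimated correlation). The chemokine Ccl2 was at 1.72 ± 0.10, Il1b at 1.81 ± 0.21 and Tnf at 1.55 ± 0.11. Interferon response genes were higher in 22 of 30 with 0 lower, 24 when adjusted over the list alone (median 0.60, or 0.32 with macrophage-gene scaling; camera adjusted p = 9.04e-05; adjusted p = 0.3 with an estimated correlation). The chemokine Cxcl10 was at 1.79 ± 0.17. Lysosome genes were higher in 25 of 31 and lower in 1, the same when adjusted over the list alone (median 0.38, or 0.19 on the TPM scale and 0.098 with macrophage-gene scaling, where 14 were higher and 8 lower; camera adjusted p = 4.54e-12; adjusted p = 0.222 with an estimated correlation). Genes of disease-associated microglia were higher in 18 of 28 and lower in 7, the same when adjusted over the list alone (median 0.56, or 0.28 with macrophage-gene scaling; camera adjusted p = 0.000502; adjusted p = 0.245 with an estimated correlation). Gpnmb was at 1.23 ± 0.06, Trem2 at 0.32 ± 0.04 and the receptor kinase Axl at −0.88 ± 0.05, with Trem2 at 0.041 and not called with macrophage-gene scaling. Proliferation genes were lower in all 26, also when adjusted over the list alone (median −0.98, camera adjusted p = 1.96e-12; adjusted p = 0.0403 with an estimated correlation). Mki67 was at −1.54 ± 0.09 and Ccna2, cyclin A2, at −1.70 ± 0.11. Integrated and unfolded protein stress genes were higher in 11 of 23 and lower in 3, the same when adjusted over the list alone, with a median of 0.11 that was −0.060 on the TPM scale, −0.032 with library totals and −0.17 with macrophage-gene scaling (camera adjusted p = 0.03). That call was lost at adjusted p = 0.269 with an estimated correlation. P2ry12 (−1.26 ± 0.09) and the fractalkine receptor Cx3cr1 (−1.59 ± 0.08) were lower in a homeostatic list that did not pass (4 higher and 8 lower of 19, or 3 and 14 with macrophage-gene scaling; camera adjusted p = 0.162). Stab2, among the largest rises with myelin, was lower with atorvastatin than with myelin (−2.86 ± 0.12).

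Between atorvastatin and myelin 7120 genes passed 5% by edgeR, 3512 higher and 3608 lower, with 337 higher and 1315 lower by at least 2-fold. The split was 2727 and 4247 with DESeq2 size factors, 1530 and 5225 with limma on TPM, 1961 and 5308 with library totals and 1001 and 6926 with macrophage-gene scaling. The last 3 moved the median of all genes by −0.17, −0.14 and −0.28.

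**Figure D3:**
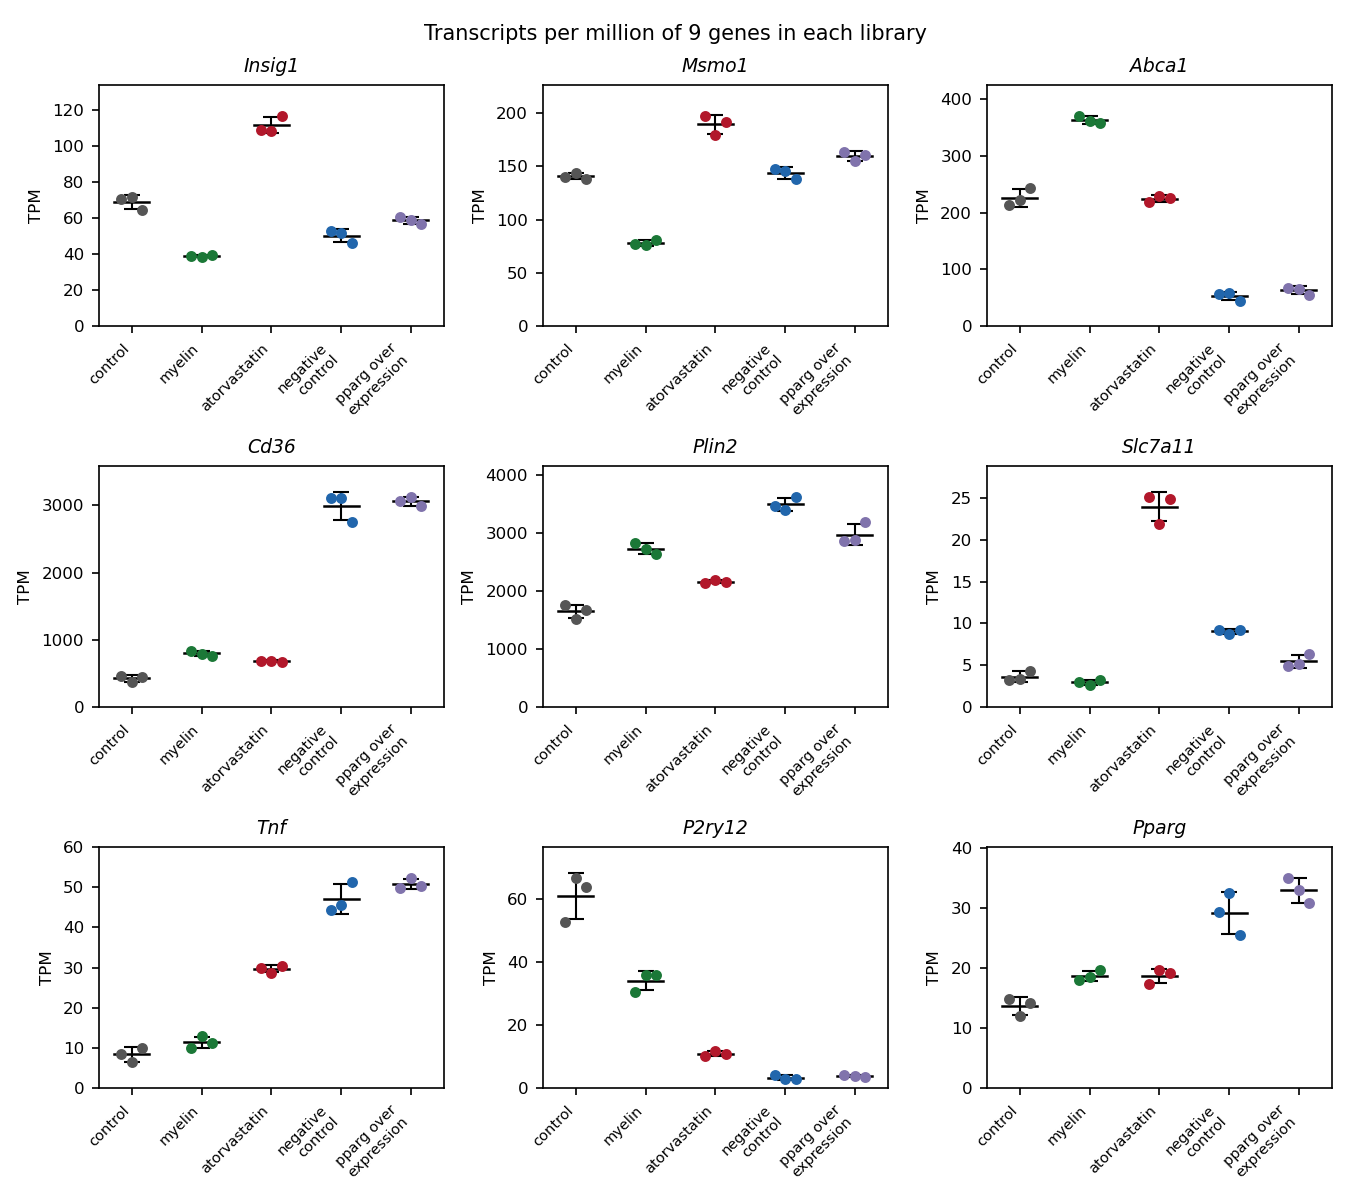
TPM of 9 genes in each library, by group; points are libraries, horizontal bars the mean of 3 and vertical bars the SD, and each vertical axis starts at 0. Insig1 lay at 38.8 TPM with myelin and 111 with atorvastatin against 68.9 in control, P2ry12 at 61.1 TPM in control and 10.96 with atorvastatin, and Pparg lay at 29.1 TPM in negative control and 32.9 in the libraries labelled pparg over expression.

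In the libraries labelled pparg over expression, set against negative control, phagocytic and homeostatic microglia transcripts were higher, as were sterol and fatty acid synthesis transcripts, by modest amounts. These list calls rest on a preset correlation between genes, and 0 of the 20 lists passed camera with an estimated one. Stab1, a scavenger receptor, was at 171 ± 10.1 against 105 ± 15.01 TPM (0.76 ± 0.07, edgeR adjusted p = 3.48e-07). C1qa, a subunit of complement C1q, was at 1139 ± 104 against 732 ± 95.7 TPM (0.70 ± 0.07, edgeR adjusted p = 2.56e-06). The desaturases Scd2 and Scd1 were higher by 0.89 ± 0.06 and 1.21 ± 0.13. The PPAR target list did not pass (2 of 19 higher, 0 lower, median 0.09, camera adjusted p = 0.906). Of its best known members, Cd36 was at 0.09 ± 0.07 (edgeR adjusted p = 0.486), Fabp4 at −0.06 ± 0.08 (edgeR adjusted p = 0.689) and Plin2 at −0.16 ± 0.06 (edgeR adjusted p = 0.0629), the last called lower in 11 alternatives. Lpl was higher by 0.49 ± 0.08 and Ucp2 by 0.29 ± 0.04. The annotated PPAR signaling pathway, chosen after its values were seen, was higher in 17 of 51 genes and lower in 1 (median 0.12). It passed camera (adjusted p = 0.00734), but not with an estimated correlation (adjusted p = 0.151). Scd2 and Scd1 had the smallest p among its higher genes.

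Phagocytic receptors were higher in 15 of 25 with 0 lower, 19 when adjusted over the list alone (median 0.24, camera adjusted p = 2.19e-11; adjusted p = 0.0975 with an estimated correlation). Axl was at 0.65 ± 0.06. Homeostatic microglia genes were higher in 13 of 19 and lower in 1 (14 and 2 when adjusted over the list alone; median 0.29, or 0.21 with macrophage-gene scaling with 8 higher and 1 lower; camera adjusted p = 1.47e-07; adjusted p = 0.0975 with an estimated correlation). C1qc was at 0.61 ± 0.07, and P2ry12 did not pass (0.36 ± 0.14, edgeR adjusted p = 0.101). Genes of disease-associated microglia were higher in 10 of 28 and lower in 2 (12 and 3 when adjusted over the list alone; median 0.14, or 0.080 on the TPM scale and 0.064 with macrophage-gene scaling; camera adjusted p = 0.01; adjusted p = 0.377 with an estimated correlation). The chemokine Ccl6 was at 1.004 ± 0.13 and Trem2 at 0.05 ± 0.04 (edgeR adjusted p = 0.501). Cholesterol synthesis genes were higher in 9 of 20 with 0 lower, 15 when adjusted over the list alone (median 0.23, or 0.16 with macrophage-gene scaling with 4 higher; camera adjusted p = 3.56e-06; adjusted p = 0.0975 with an estimated correlation). Cyp51 was at 0.30 ± 0.05. SREBP2-regulated uptake genes were higher in 5 of 6, also when adjusted over the list alone (median 0.26, or 0.19 with macrophage-gene scaling with 1 higher, against 2 on the TPM scale and 3 with library totals; camera adjusted p = 0.00187; adjusted p = 0.0975 with an estimated correlation). Efflux and LXR targets were higher in 8 of 15 with 0 lower, also when adjusted over the list alone (median 0.22, or 0.15 with macrophage-gene scaling with 4 higher; camera adjusted p = 1.33e-05; adjusted p = 0.0975 with an estimated correlation). Pltp was at 0.51 ± 0.06, Abcg1 at 0.41 ± 0.07, Abca1 at 0.31 ± 0.07 and Apoe at 0.26 ± 0.04, with Abca1 at 0.25 and not called on the TPM scale. Fatty acid synthesis genes were higher in 7 of 15 with 0 lower, also when adjusted over the list alone (median 0.17, or 0.093 with macrophage-gene scaling with 4 higher; camera adjusted p = 0.000196; adjusted p = 0.0975 with an estimated correlation).

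Interferon response genes were higher in 10 of 30 with 0 lower, 16 when adjusted over the list alone (median 0.64, or 0.26 on the TPM scale; camera adjusted p = 9.73e-08; adjusted p = 0.219 with an estimated correlation). Rtp4 was at 1.49 ± 0.29 and Ifit3 at 1.39 ± 0.28. Proliferation genes were higher in 14 of 26, also when adjusted over the list alone (median 0.45, or 0.37 with macrophage-gene scaling with 9 higher; camera adjusted p = 9.73e-08; adjusted p = 0.0975 with an estimated correlation). Their levels were low, with Mki67 at 1.37 ± 0.33 against 0.46 ± 0.20 TPM. Interferon and proliferation genes, like astrocyte markers, were mostly far lower in negative control than in control. Astrocyte markers were also higher in the libraries labelled pparg over expression. Whether carry-over of cells or RNA like the control cultures gives the rise of the interferon and proliferation lists was not tested. NRF2 oxidative stress genes were lower in 5 of 18 and higher in 2 (7 and 3 when adjusted over the list alone; median −0.10, or −0.16 on the TPM scale and −0.18 with macrophage-gene scaling; camera adjusted p = 0.0119; adjusted p = 0.377 with an estimated correlation). Slc7a11 was at −0.64 ± 0.09. Glycolysis genes were lower in 5 of 19 and higher in 2 (8 and 3 when adjusted over the list alone; median −0.07, or −0.13 on the TPM scale and −0.15 with macrophage-gene scaling; camera adjusted p = 0.0186; adjusted p = 0.347 with an estimated correlation). The stress list did not pass as one (6 higher and 9 lower of 23, camera adjusted p = 0.123). The chaperones Calr (0.49 ± 0.04) and Hspa5 (0.35 ± 0.04) were higher, while Chac1 (−1.19 ± 0.28) and Trib3 (−0.82 ± 0.14), which ATF4 induces, were lower. Lysosome genes (5 higher and 2 lower of 31, camera adjusted p = 0.362), fatty acid oxidation (2 and 1 of 22, 0.467), lipid droplet (2 and 1 of 18, 0.248), pro-inflammatory genes (5 and 1 of 25, 0.0969), alternative activation (2 and 0 of 10, 0.0969) and oxidative phosphorylation (0.467) did not pass camera either. The lysosome split turned to 1 higher and 9 lower on the TPM scale, 3 and 10 with library totals and 1 and 5 with macrophage-gene scaling. On the TPM scale 0 fatty acid oxidation and 0 lipid droplet genes were higher, and 2 and 3 lower. Beyond the biology lists the largest rises were Serpina3n (1.53 ± 0.22), Cd5l (1.39 ± 0.16), Folr2 (1.38 ± 0.17, of the border macrophage and monocyte markers) and Ifitm3 (1.251 ± 0.14). The largest falls were Zfp969 (−0.81 ± 0.26, not past the threshold by the Wald test, with limma on TPM or in 5 of the 6 fits without 1 library), Slc25a25 (−0.73 ± 0.10) and Ifrd1 (−0.64 ± 0.07).

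Markers of other cells moved with these groups. Astrocyte markers were higher in 9 of 12 with 0 lower, 11 when adjusted over the list alone (median 0.95, camera adjusted p = 1.32e-12; adjusted p = 0.0242 with an estimated correlation). Oligodendrocyte and myelin markers were higher in 3 of 14, 6 when adjusted over the list alone (median 0.80, camera adjusted p = 0.000165; adjusted p = 0.0709 with an estimated correlation). Border macrophage and monocyte markers were higher in 4 of 6, also when adjusted over the list alone (median 0.36, camera adjusted p = 0.000301; adjusted p = 0.0709 with an estimated correlation). The mannose receptor gene Mrc1 was at 0.42 ± 0.06, and Folr2, given above among the largest rises, was another of the higher members. Transcripts of the mitochondrial genome were higher in 11 of 13, all 13 when adjusted over the list alone (median 0.28, camera adjusted p = 3e-10; adjusted p = 0.0855 with an estimated correlation). Immediate early genes were higher in 5 of 12 and lower in 1 (6 and 1 when adjusted over the list alone; median 0.36, camera adjusted p = 0.00517; adjusted p = 0.125 with an estimated correlation). Neuron markers (median 1.13), fibroblast markers (−1.06) and endothelial and mural markers (−0.35) also passed camera (adjusted p = 0.0204, 0.00244 and 0.0463), from sums of 2.85, 7.92 and 34.3 TPM in negative control, and not with an estimated correlation (adjusted p = 0.146, 0.152 and 0.125). The neuron sums were 3.88, 3.66 and 7.73 TPM in pparg over expression replicates 1, 2 and 3, so that this rise rested largely on replicate 3. Neutrophil and lymphocyte markers, with 1 measured gene, and erythrocyte markers, with 0, were not tested.

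Between these groups 1595 genes passed 5% by edgeR, 1124 higher and 471 lower; 202 were higher and 9 lower by at least 2-fold. The split was 565 and 696 with limma on TPM, 839 and 960 with library totals, 499 and 547 with macrophage-gene scaling and 924 and 666 when only these 2 groups were fitted. Without negative control replicate 3, 998 genes passed.

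Negative control libraries differed from control libraries in most genes, although both were labelled as controls. Sparc and Gpr34, of the homeostatic microglia list, went from 1404 ± 147 to 19.7 ± 1.29 TPM (−5.72 ± 0.11) and from 119 ± 5.92 to 1.87 ± 0.45 TPM (−5.62 ± 0.11), both at edgeR adjusted p = 3.8e-21. Control libraries held far more transcripts of other cell types, so changes between these groups cannot be assigned to microglia alone. P2ry12 changed by −3.54 ± 0.11. Cd36 rose from 435 ± 52.3 to 2996 ± 210 TPM (3.16 ± 0.08, edgeR adjusted p = 7.98e-20), Lgals3 by 2.84 ± 0.06 and Plin2 by 1.45 ± 0.06. Pparg rose by 1.47 ± 0.10 and Tnf by 2.87 ± 0.11, while Apoe fell (−0.79 ± 0.04) and Abca1 fell (−1.71 ± 0.08).

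Homeostatic microglia genes fell in 14 of 19 and rose in 4, the same when adjusted over the list alone (median −0.58, or −0.995 on the TPM scale and −1.53 with macrophage-gene scaling; camera adjusted p = 0.00848; adjusted p = 0.371 with an estimated correlation). Interferon response genes fell in 27 of 30 with 0 rising, also when adjusted over the list alone (median −2.37, camera adjusted p = 1.25e-06; adjusted p = 0.371 with an estimated correlation). Ifit2 was at −4.26 ± 0.17. Proliferation genes fell in 24 of 26 and rose in 1, the same when adjusted over the list alone (median −3.05, camera adjusted p = 1.1e-07; adjusted p = 0.371 with an estimated correlation). Fatty acid synthesis fell in 11 of 15 and rose in 2, the same when adjusted over the list alone (median −2.18, or −1.14 on the TPM scale; camera adjusted p = 0.0195; adjusted p = 0.371 with an estimated correlation). Scd1 was at −3.81 ± 0.10. Lysosome genes (28 rose and 2 fell of 31), NRF2 oxidative stress genes (13 and 3 of 18), glycolysis genes (16 and 2 of 19) and oxidative phosphorylation genes (25 and 0 of 27) rose, with the same counts when adjusted over the list alone (camera adjusted p = 9.35e-09, 0.00828, 0.000607 and 2.07e-05). None of the 4 calls held (adjusted p = 0.371, 0.426, 0.371 and 0.371 with an estimated correlation). Their medians of 0.86, 0.69, 0.38 and 0.37 turned to −0.08, −0.25, −0.56 and −0.58 with macrophage-gene scaling, and the last was −0.0037 on the TPM scale, where the others were 0.48, 0.29 and 0.051. Trib3 (4.45 ± 0.19) and Asns (2.66 ± 0.06), both ATF4 targets, rose in a stress list that did not pass (14 rose and 7 fell of 23, or 9 and 13 with macrophage-gene scaling; camera adjusted p = 0.0678). Astrocyte markers fell in 12 of 12 and oligodendrocyte and myelin markers in 14 of 14, also when adjusted over the list alone (medians −5.17 and −5.01, camera adjusted p = 1.9e-06 and 1.45e-05; adjusted p = 0.0836 and 0.0667 with an estimated correlation). These falls stand beside those of the proliferation, interferon and homeostatic lists.

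Between negative control and control 11150 genes passed 5% by edgeR, 5475 higher and 5675 lower, with 920 higher and 3901 lower by at least 2-fold. The split was 2848 and 7147 with limma on TPM, 3585 and 7296 with library totals and 608 and 11555 with macrophage-gene scaling, which moved the median of all genes by −0.35, −0.28 and −0.94. The genes with the largest falls were at or near 0 counts in negative control libraries, so their fitted folds are not given, and the labels name no step other than the group that could set these libraries apart.

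The fold changes of myelin and of atorvastatin against control correlated across 13630 genes at Pearson r = 0.601 and Spearman correlation 0.680, where genes are not independent replicates. Both used the same control libraries. In 10 simulations the control, myelin and atorvastatin libraries were all drawn from the control means, with r = 0.490 and Spearman 0.446 on average. Particular deviations of the real control libraries are therefore not in these simulations. The covariance was 0.182 against 0.0163 in the simulations, a difference of 0.166. Of the genes higher with myelin, 1780 were also higher with atorvastatin (705 for independent lists), 1387 were lower in both (519 for independent lists). Another 103 and 70 went opposite ways (673 and 544 for independent lists), and the simulations gave at most 1 shared call in the same direction. That count cannot bound the part of the shared calls due to the controls, because the simulated groups held no changed genes to be called. The 3 controls cannot be split into 2 groups of at least 2, so part of the excess may come from the shared controls. Cell-type markers also moved the same way in both groups. Astrocyte markers summed to 1682 TPM in control, 1331 with myelin and 719 with atorvastatin. The 20 macrophage genes had median log2 folds of 0.33 with myelin and 0.59 with atorvastatin. Whether the excess reflects this shared shift of the mixtures or the treatments was not tested. Cholesterol synthesis genes such as Msmo1 were among those that went opposite ways, lower with myelin and higher with atorvastatin. The fold changes of the libraries labelled pparg over expression against negative control, which share no library with the other comparisons, correlated with those of myelin against control at r = −0.0853 (Spearman −0.101). The correlation with atorvastatin against control was r = −0.207 (Spearman −0.215) and with atorvastatin against myelin r = −0.209 (Spearman −0.244). Without the 3901 genes at least 2-fold higher in control than in negative control, the first turned to r = 0.197 and the second to 0.0917, and without pparg over expression replicate 3 the first was 0.00764. Of genes higher in the libraries labelled pparg over expression, 388 were higher (177 for independent lists) and 254 lower (137) with myelin, and of those lower there, 120 were higher (74.3) and 45 lower (57.3). With atorvastatin against control, 427 of the higher genes were higher (369) and 506 lower (352), and of the lower genes 286 were higher (154) and 81 lower (147). With atorvastatin against myelin, these were 279 (290) and 551 (298), and 261 (121) and 58 (125).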

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

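The scalings on library totals and on macrophage genes, and the runs without genes high in control cultures, were chosen only after the data were seen; the others were planned. All gene counts and list counts not given here stayed within 1.5 times their value under the alternatives run. With a fold of at least 2 required, 125, 2580, 1652, 211 and 4821 genes passed for myelin against control, atorvastatin against control, atorvastatin against myelin, pparg over expression against negative control, and negative control against control. Testing the genes above the median in mean count alone gave 4545 (atorvastatin against control), 3896 (atorvastatin against myelin) and 5534 (negative control against control), with fewer genes tested. Without genes high in control cultures 2425 (myelin against control), 5361 and 4435 (atorvastatin against control and against myelin) passed, again with fewer genes. Macrophage-gene scaling gave 8519 for myelin against control and 1046 for pparg over expression against negative control; the cause was not tested. With an estimated correlation 6, 0, 5, 0 and 0 of the 20 lists passed camera in the order above, against 13, 12, 13, 11 and 8, and fry gave 16 for negative control against control. A pseudocount of 0.1 does not apply to a count test and was not run.

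Leaving out 1 library at a time gave 2636 to 3747, 7816 to 8236, 6407 to 6714, 998 to 1385 and 10808 to 11015 genes in that order, the 998 without negative control replicate 3, and 13 to 13, 12 to 12, 12 to 13, 9 to 11 and 8 to 9 lists. The log2 fold of Pparg ranged from 0.17 to 0.32. The correlation of fold changes between pparg over expression and myelin, −0.0853 in all genes, was −0.00198 in genes above the median count, 0.197 without genes high in control cultures, and −0.113 to 0.00764 without 1 library, above 0 without pparg over expression replicate 3. That with atorvastatin against control was −0.244, 0.0917, and −0.250 to −0.121. That with atorvastatin against myelin was −0.307, −0.0122, and −0.240 to −0.149. That of myelin with atorvastatin against control was 0.654, 0.524, and 0.513 to 0.626. The cause was not tested.

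For 175 values of single genes, 2607 of 2675 alternative values kept direction and side of the threshold, 29 lost the call, 22 gained one and 17 reversed. The cause of the reversals was not tested. Apoe between atorvastatin and myelin was −0.058 with DESeq2 size factors and −0.058 with the Wald test, −0.18 on the TPM scale, −0.081 in genes above the median count, −0.14 with library totals, −0.27 with macrophage-gene scaling, −0.087 without genes high in control cultures, and −0.015 (without myelin replicate 3) to 0.018 without 1 library, with −3.68e-05 without atorvastatin replicate 1. Apoe was called lower there on the TPM scale, with library totals and with macrophage-gene scaling. Pparg between atorvastatin and myelin was −0.0022 on the TPM scale and −0.13 with macrophage-gene scaling. Against control with atorvastatin, Abca1 was −0.0075 on the TPM scale and −0.31, called lower, with macrophage-gene scaling, and Trem2 was −0.040 with the latter. Trem2 was −0.081 with macrophage-gene scaling for myelin against control, and for pparg over expression against negative control −0.0057 on the TPM scale and −0.022 with macrophage-gene scaling. In the latter comparison Plin2 gained a call in 11 alternatives (edgeR adjusted p = 0.0489 with the replicate block) and Zfp969 lost it in 7, among them without any 1 of negative control replicates 1 to 3 or pparg over expression replicates 2 and 3. Abca1 there lost it on the TPM scale (0.25) and without negative control replicate 3 (0.21) or pparg over expression replicate 1 (0.26), and P2ry12 gained one without negative control replicate 1 (0.51). Rsc1a1 lost its call for myelin by the Wald test (2.06) and without control replicate 2 (1.60), control replicate 3 (1.49) or myelin replicate 1 (1.90). For atorvastatin against control, Abca1 lost its call by the Wald test (0.20), in genes above the median count (0.15), with library totals (0.048) and without control replicate 1 (0.17) or 2 (0.18). Lpl there was called lower on the TPM scale (−0.34), with library totals (−0.29), with macrophage-gene scaling (−0.65), without genes high in control cultures (−0.19) and without control replicate 2 (−0.22). Cd36 between atorvastatin and myelin gained a call, as lower, in 5 alternatives (−0.37 to −0.18). Macrophage-gene scaling alone ended the calls of Lpl, Fabp4, Hadha and Tnf for myelin against control. It also ended those of Msmo1, Apoe, Pparg and Plin2 for atorvastatin against control, of Trem2 for atorvastatin against myelin and of Rplp0 for negative control against control.

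Whether replicate numbers pair libraries is not settled. Over all groups 3 of 30 correlations between libraries of the same number, after removing group means, were above 0.1 (−0.0254 to 0.137), and 1 of 15 libraries correlated best with its own number in every other group. The 3 were control 1 with myelin 1 (0.118), control 3 with atorvastatin 3 (0.137) and atorvastatin 1 with myelin 1 (0.107). Control 2 with myelin 2 was at −0.0097. The median was 0.0106 for the same number and −0.0085 for other numbers. With the replicate number as a block 3899, 8740, 7136, 1677 and 11161 genes passed, the list counts were the same, and of the genes named only Plin2 changed its side of the threshold.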

Other observations

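In this part the pathways and their genes were chosen after their values were seen, as were all tests of explanations except the splits of the libraries and the exchange of some libraries between groups. Of 305 pathways annotated in the deposited table, 45, 75, 63, 52 and 44 passed camera at 5% for myelin against control, atorvastatin against control, atorvastatin against myelin, pparg over expression against negative control, and negative control against control, and each of these calls was lost with an estimated correlation between genes. Complement and coagulation genes were higher in 13 of 41 in the libraries labelled pparg over expression (median 0.31, camera adjusted p = 0.000784; adjusted p = 0.151 with an estimated correlation). The median stayed above 0 under each of the 4 other scalings. C1qb was at 0.59 ± 0.07 and the anaphylatoxin receptor C5ar1 at 0.49 ± 0.06 (n = 3 each). Ribosome biogenesis genes were lower in 9 of 71 and higher in 1 in the same libraries (median −0.07, camera adjusted p = 0.000147; adjusted p = 0.166 with an estimated correlation). Utp18 was at −0.38 ± 0.06.

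Extracellular matrix and receptor genes fell in 28 of 66 and rose in 7 with myelin (median −0.28, camera adjusted p = 0.0116; adjusted p = 0.56 with an estimated correlation). The matrix genes Tnc and Thbs2 were at −0.93 ± 0.09 and −0.99 ± 0.11. The same pathway fell in 56 of 66 and rose in 7 in negative control against control (camera adjusted p = 7.09e-07; adjusted p = 0.433 with an estimated correlation). It stood beside falls in 12 of 12 astrocyte and 8 of 9 fibroblast markers. DNA replication genes were lower in 22 of 35 and higher in 2 with atorvastatin against myelin (median −0.30, camera adjusted p = 0.000504; adjusted p = 0.29 with an estimated correlation). Beside them 11 of 12 astrocyte and 12 of 14 oligodendrocyte and myelin markers were lower. The helicase subunit Mcm5 was at −1.27 ± 0.09 and Mcm2 at −0.86 ± 0.06. Glycan degradation genes rose in 11 of 16 with myelin (median 0.28, or −0.04 with macrophage-gene scaling; camera adjusted p = 3.44e-07, and adjusted p = 0.467 with an estimated correlation). Engase rose by 0.94 ± 0.09. Mitophagy genes rose in 47 of 67 and fell in 7 with atorvastatin against control (median 0.29, but −0.02 on the TPM scale and −0.32 with macrophage-gene scaling; camera adjusted p = 1.33e-05, and adjusted p = 0.323 with an estimated correlation). The autophagy receptors Bnip3l and Sqstm1 rose by 1.148 ± 0.04 and 1.21 ± 0.06. Ribosomal protein genes rose in 120 of 128 and fell in 2 in negative control against control (median 0.69, or −0.25 with macrophage-gene scaling; camera adjusted p = 3.65e-15, and adjusted p = 0.465 with an estimated correlation). Rplp0 was at 1.04 ± 0.04, or 0.097 and not called with macrophage-gene scaling.

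For each comparison the 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05, and 1 of the 10, the real one, gave a count as large. The real split and the highest of the others gave 3810 and 1 genes for myelin against control, 8735 and 0 for atorvastatin against control, 7120 and 0 for atorvastatin against myelin, 1595 and 1 for pparg over expression against negative control, and 11150 and 0 for negative control against control.

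In atorvastatin libraries NRF2 oxidative stress genes were higher and proliferation genes lower than in control (camera adjusted p = 1.65e-08 and 6.76e-11), and both calls were lost at adjusted p = 0.118 with an estimated correlation. A larger share of microglial RNA would raise all microglial genes alike, but the NRF2 median lay 0.71 above that of 20 macrophage genes (1.299 against 0.59, SD 0.50, permutation p = 0.00028 over genes, 18 against 20). Genes are not independent replicates, so this p may overstate the certainty. The 20 macrophage genes themselves ranged from −0.91 to 1.26. The gap between the medians therefore argues only weakly against a larger share as the whole cause. The choice of scaling is argued against by a lowest median of 0.68 over the other 4 scalings, with macrophage-gene scaling, a value that rests on the same 20 genes. The proliferation median of −1.38 (SD 0.47) lay between those of astrocyte markers (−1.06, SD 0.68) and oligodendrocyte markers (−2.29, SD 1.02), so that a fall in dividing microglia and a loss of dividing cells of other types cannot be told apart, because the libraries are mixtures. A response of microglia to atorvastatin, which the design names, stays open and was not tested, and whether cells also had myelin is not known.

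Pparg was at most slightly higher in the libraries labelled pparg over expression. An exchange of some libraries between this group and negative control would leave those nearer the other group, and 0 of the 6 were, which argues against it, while an exchange of the groups as a whole would not show in this test. A transgene whose reads were not assigned to Pparg, for example one of another species or without the native ends, might leave the level low, and the PPAR target median of 0.086 (2 of 19 higher) neither needs nor rules out such a transgene. The annotated PPAR signaling pathway was higher in 17 of 51 genes, but passed camera only with the preset correlation, and does not settle it either. The 2 cannot be told apart, a construct with no effect on the receptor and one that the table does not count, because the sequence of the construct is not in the labels.

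Homeostatic and phagocytic genes were higher in the same libraries, in 13 of 19 and 15 of 25 members (camera adjusted p = 1.47e-07 and 2.19e-11), and both calls were lost at adjusted p = 0.0975 with an estimated correlation. Of the 44 members 32 were not 2-fold lower in negative control than in control, and 19 of these passed as higher and 1 as lower; as the whole cause of their rise as a set, carry-over of cells or RNA like the control cultures is argued against, since the share that astrocyte markers give, 2.20%, falls short by a median log2 fold of 0.22 (quartiles 0.11 to 0.37), with 29 of the 32 above the fold it gives. Of the 12 members at least 2-fold lower in negative control than in control, 6 lay more than 2 SE from the fold that this share gives, with 4 above it, such as C1qa (a share of 31.0% needed) and Stab1 (17.1%), and 2 below it, Sparc (0.761%) and Gpr34 (0.819%), so that for these 12 carry-over is left open as a part of the cause. The share and the folds it gives are on the TPM scale, and the observed folds on the TMM scale. Limma on TPM moved the median of all genes by −0.057, so the shortfalls above are somewhat overstated. The SE also leaves out the spread of the astrocyte markers, and Fcgr2b (0.17 against 0.046, SE 0.052) counts as above by a narrow margin. By their selection, carry-over gives the 32 members little rise (median log2 fold 0.0030, against 0.23 observed). The 20 macrophage genes also rose in this comparison (median 0.13, SD 0.15, 9 higher and 0 lower). The shortfall of carry-over therefore does not make the rise particular to these lists. The choice of scaling is argued against by a lowest list median of 0.16 (phagocytic genes with macrophage-gene scaling, 10 higher). An effect of the over expression construct, which the design names, stays open and was not tested, and the labels cannot separate it from any other difference in how the 2 groups were grown.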
